A study of Mus musculus with 72 samples.

How the data were processed

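Mature miRNAs were counted in small RNA libraries from left cortex, left striatum and right cerebellum of male wild-type and Thap1+/- mice, naive or 12 weeks after a 1 min crush of the right sciatic nerve at 12 weeks of age. Libraries were made from 10 ng of RNA with a QIAseq miRNA kit, per the labels' protocols. RNA came from a miRNeasy mini kit for cerebellum and a micro kit for cortex and striatum, per the labels' protocols, so the kit cannot be told apart from the cerebellum. The labels list 72 samples, 6 biological replicates in each of 12 groups. The 12 deposited tables held 71 libraries, and 1 wild-type naive cortex library was not analysed here. Each table held the counts of every library of its region with the authors' results for 1 comparison, and the counts did not differ between the 4 tables of a region. Libraries were assigned to groups by their column names, and the number that ends a column name could not be matched to a single title in the labels. Single libraries are named by their column, as CX_DYT6KO_naive_18, where CX, STR and CB are cortex, striatum and cerebellum and DYT6KO stands for Thap1+/-. The tables held 284 further columns of per-sample values that were not used.

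The count columns hold whole numbers per mature miRNA, deposited without normalization, as their totals differ between libraries. The authors counted with featureCounts 1.6.4 and used R 4.1.0, per the submitters' processing notes. The aligner, miRNA annotation and genome build of the authors are not given in the sources used here, nor is whether unique molecular identifiers were collapsed. The deposited tables also hold the authors' mean signal per miRNA, log2 fold changes, their standard errors, a test statistic (score), p-values and adjusted p-values from DESeq2, per the file headers. Of these, the authors' deposited adjusted p-values and log2 fold changes were read only to compare calls and fold changes, and the authors' signal and score columns were not used for any result.

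Totals ran from 7479448 to 12589140 counts per library, with a mean of 10277846 ± 1233073 (SD, n = 71). Replicates of a group were compared for duplicates. The least different pair, in cerebellum Thap1+/- crush, differed with a chi-square per degree of freedom of 11.9, well above sampling noise, so every library counted as 1 replicate.

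Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) after TMM scaling, edgeR's filterByExpr filter and Benjamini-Hochberg adjustment over the miRNAs tested, with calls at 0.05. The filter left 549 miRNAs in cortex, 575 in striatum and 552 in cerebellum of 1927. All libraries of a region entered 1 fit with its 4 groups, and the contrasts were genotype in naive and in crushed mice, crush in each genotype, their difference (the interaction) and the averages. The 17 naive wild-type libraries were tested between regions in a fit of their own, on 579 miRNAs. The effect of crush or genotype was also compared between regions in a joint fit, which was not in the original design. Standard errors are the absolute log2 fold change over the square root of F. Levels are edgeR's CPM, each count scaled to a common library total after TMM scaling. All tests are two-sided, and 24 comparisons were made, not counting those of the joint fit between regions. No paired fit was used, because the groups compared within a region share no library number and the labels give no animal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

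The text names miRNAs by a rule. Where a comparison within a region had at most 20 calls all were eligible, and otherwise the 10 higher and 10 lower with the smallest p among those with a mean of at least 10 CPM. With fewer than 3 calls, the 5 smallest p were added as not passing. Between regions the 10 largest changes each way with a mean of at least 100 CPM were eligible. The members of a list that passed adjusted over the list alone, its most abundant members and the 5 most abundant miRNAs of each region were added. The same miRNA name can stand for several gene copies. let-7 members differ by few bases, and let-7, miR-9, miR-30c, Sfmbt2 and other multicopy miRNAs have near-identical sequences, so how counts divide among them is uncertain. Names joined by a slash are single features of the deposited tables.

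There were 18 lists of miRNAs: neuron-enriched, activity-regulated, oligodendrocyte, astrocyte, microglia and inflammation, red cell, vessel, choroid plexus and ependyma, muscle, Hox cluster, mitochondria and energy metabolism, nerve injury, dopamine and striatum, let-7 with miR-98, miR-17-92, miR-183, Dlk1-Dio3 and Sfmbt2. Lists with at least 3 tested members were tested with camera (preset correlation of 0.01) and fry, each adjusted over the lists of a comparison. camera compares a list with the other miRNAs. fry's main p tests whether members move on balance one way and its mixed p, adjusted alike, whether they change in either direction, and neither compares with other miRNAs. camera called 49 of 404 list tests, of which 0 held when the correlation among members was estimated. The median, mean and camera direction differed in sign in 82 tests, 0 of them called by camera. In wild-type cortex after crush this held for the astrocyte, vessel, choroid plexus and dopamine lists. Lists overlap: 15 members of the nerve injury list are also in another list, 7 of the mitochondrial, 7 of the dopamine, 6 of the activity-regulated, 6 of the Dlk1-Dio3, 5 of the microglia, 4 of the muscle, 3 of the astrocyte, 3 of the miR-183, 2 each of the neuron, oligodendrocyte and vessel, and 1 of the choroid plexus list.

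The fits were tested on simulated counts with 100 miRNAs changed by 1.5-fold and 100 by 2-fold, and recovered 57 and 81 with 3 false calls for genotype in naive cortex, 45 and 79 with 3 false calls in naive striatum, 57 and 90 with 8 false calls in naive cerebellum and 65 and 75 with 5 false calls for striatum against cortex. These counts were drawn independently for each miRNA, with the same spread in all groups. They do not show how many false calls arise where miRNAs vary together or groups differ in spread. Positions come from matching miRNA names to hairpin genes of GRCm38 (GENCODE vM21), where 1739 of 1927 names matched 1 gene, 81 several and 107 none. Alternatives tried were RLE in place of TMM scaling, no filter and a stricter filter (10 CPM in 6 libraries), the DESeq2 1.42.0 Wald test, fits on only the 2 groups compared, leaving out each library in turn, camera with an estimated correlation and the library number as a replicate block between regions. Principal components came from the log2 CPM of the tested miRNAs of a region, centred and not scaled. Counts over random divisions of the libraries were adjusted over the 24 comparisons by the Benjamini-Hochberg method. Chosen after seeing the data were that block for the effects compared between regions and fits without let-7 and miR-98 and without the libraries that stand apart, namely CX_DYT6KO_naive_16 and CX_DYT6KO_naive_18, STR_DYT6KO_crush_8, and CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86. In places a number of calls is given as the percentage of the miRNAs tested in that fit. Whether a number of calls moved was always decided on the counts.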

Results

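Small RNA was sequenced from the left cortex, left striatum and right cerebellum of male wild-type mice and of Thap1+/- mice, which carry 1 inactive copy of Thap1, the transcription factor gene mutated in DYT6 dystonia. Part of the mice of each genotype had their right sciatic nerve crushed for 1 min at 12 weeks of age and were sampled 12 weeks later, and the others were left uninjured (naive). The question was which miRNAs in brain regions relevant to dystonia differ with the genotype, with the nerve injury, and with both. Counts were analysed from 71 libraries in 12 groups, with 6 libraries in every group except cortex wild-type naive, which had 5. The labels call them biological replicates. A single library is named by its column in the deposited tables, where CX, STR and CB are the regions and DYT6KO stands for Thap1+/-. Each library held 7479448 to 12589140 counts over 1927 mature miRNAs. The mean total was 9347345 ± 701822 counts in cortex (SD, n = 23), 10007616 ± 1059808 counts in striatum (SD, n = 24) and 11439807 ± 826013 counts in cerebellum (SD, n = 24). Thap1 mRNA is not among the features measured, so the genotype labels could not be checked on the targeted gene. Within regions, fold changes are log2 values with their standard errors after ±, and levels are normalised counts (edgeR's CPM, scaled to a common library total) with their SDs.

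The let-7 family, which represses growth-promoting genes such as Lin28 and is abundant in mature brain, made up with miR-98 49.3% ± 4.44 of the counts in cortex (SD, n = 23), 45.8% ± 2.54 in striatum (n = 24) and 62.4% ± 5.01 in cerebellum (n = 24). let-7c-5p was the most abundant miRNA in cortex (10.6% ± 1.18 of counts, SD, n = 23) and in cerebellum (14.96% ± 1.65, n = 24). In striatum let-7f-5p (8.55% ± 0.924, n = 24), let-7c-5p (8.54% ± 0.795) and let-7a-5p (8.51% ± 0.537) were nearly equal. miR-128-3p, a neuronal miRNA, was the only one of the 5 most abundant in cortex outside the family (6.73% ± 0.973). In cortex, let-7 and miR-98 together took 55.2% ± 2.17 of the counts in wild-type naive libraries (SD, n = 5), 45.9% ± 2.64 after crush in wild type, 48.7% ± 3.80 in naive Thap1+/- and 48.2% ± 3.41 in crushed Thap1+/- libraries (n = 6 each). Striatum groups lay between 44.5% ± 1.85 in wild-type naive and 47.2% ± 1.93 in crushed Thap1+/- libraries. Cerebellum groups ran from 58.4% ± 2.25 in wild-type naive to 68.5% ± 5.49 in crushed Thap1+/- libraries. Because this family carries so much of each library, each comparison within a region, and between the regions in naive mice, was also made without it. Counts and splits between higher and lower that moved are given beside their comparison.

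**Figure D1:**
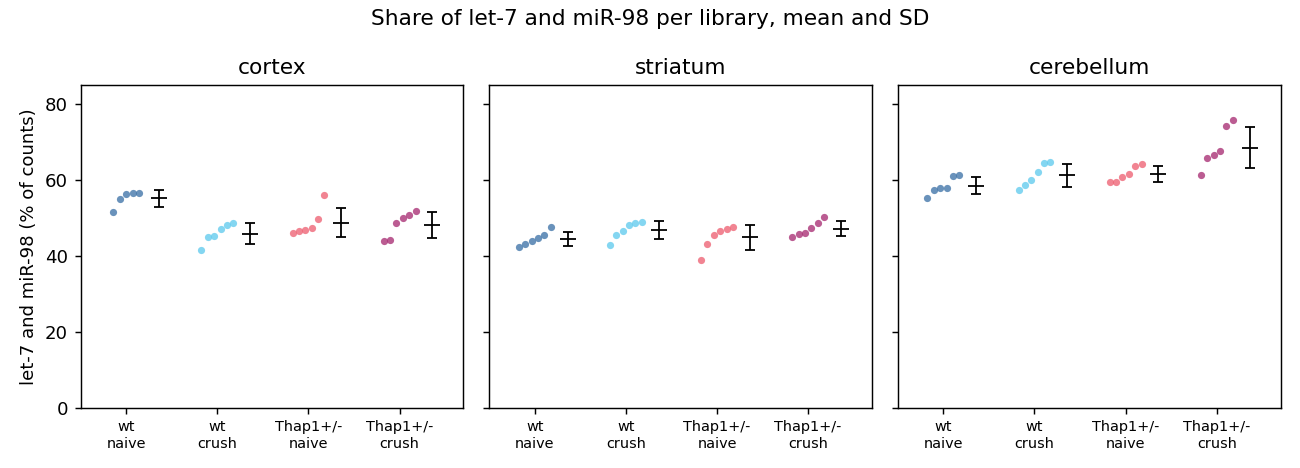
Share of let-7 and miR-98 in the counts of each library (%), by region and group, with the mean and SD beside the points. Wild-type naive cortex libraries average 55.2%, above the other cortex groups, and crushed Thap1+/- cerebellum libraries average 68.5%, above the other cerebellum groups.

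In uninjured cortex, 111 of 549 tested miRNAs differed between Thap1+/- and wild-type mice, 70 higher and 41 lower in Thap1+/- (adjusted p from edgeR's quasi-likelihood test). miR-339-5p rose from 7.35 ± 2.29 CPM (SD, n = 5) in wild type to 15.4 ± 3.20 CPM (n = 6) in Thap1+/- cortex, a log2 fold change of 1.06 ± 0.20 (adjusted p = 0.00398), and it was higher in 6 of 6 Thap1+/- libraries than the wild-type mean. miR-341-3p, from the imprinted Dlk1-Dio3 locus, rose from 658 ± 109 to 1114 ± 262 CPM (0.76 ± 0.14). miR-434-3p of the same locus rose by 1.14 ± 0.26, miR-30b-5p by 0.90 ± 0.20 and miR-15a-5p, a regulator of cell cycle genes, by 0.77 ± 0.17. miR-434-3p was higher in 4 of 6 Thap1+/- libraries, ranging from 53.6 to 190.0 CPM against a wild-type mean of 61.2, and the other 3 were each higher in 5 of 6. Among those that fell, let-7c-5p went from 137497 ± 6944 to 102611 ± 17663 CPM (-0.42 ± 0.11), miR-382-5p changed by -0.52 ± 0.11 and miR-30a-3p by -0.40 ± 0.08. By name, Mir341 lies at chromosome 12, 109611500 to 109611595 (GRCm38) inside the noncoding Rian transcript, and Mir382 at chromosome 12, 109733771 to 109733846 inside Mirg. Mir339 lies at chromosome 5, 139369650 to 139369745, inside the protein-coding gene 3110082I17Rik on the same strand.

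Of 9 let-7 and miR-98 members, 8 fell and miR-98-5p did not pass (-0.31 ± 0.13); all 9 were lower adjusted over the list alone. The family was lower as a set (camera adjusted p = 9.79e-06), but not by the test that estimates the correlation among its members (adjusted p = 0.874 with an estimated correlation). In the Dlk1-Dio3 list, 16 of 81 arms rose and 9 fell, and 21 and 11 adjusted over the list alone (camera adjusted p = 0.373). In the neuron-enriched list 4 of 13 rose, among them miR-218-5p (0.40 ± 0.10), which is enriched in motor neurons, and miR-153-3p (0.70 ± 0.19), while miR-129-5p fell (-0.41 ± 0.15). In the list of microglia and inflammation 4 of 9 rose, including miR-146b-5p (0.49 ± 0.11) and miR-146a-5p (0.44 ± 0.15), both brakes on NF-kB signalling, and the pro-inflammatory miR-155-5p fell (-0.47 ± 0.14). The list for mitochondria and energy metabolism went both ways: 5 of 21 rose and 3 fell, 7 and 4 adjusted over the list alone. miR-29a-3p (0.43 ± 0.13) and miR-15b-5p (0.58 ± 0.18) rose, and miR-16-5p, of the same family as miR-15b-5p, fell (-0.31 ± 0.08). For this list fry found change in either direction (fry mixed, adjusted p = 0.00128) but none on balance (fry adjusted p = 0.326). In the astrocyte list miR-29a-3p, miR-29b-3p (0.61 ± 0.20) and miR-29c-3p (0.56 ± 0.19) rose. CX_DYT6KO_naive_18 stood apart with a let-7 share like that of wild-type naive libraries, and the number of calls depended on it and on others. Leaving out 1 library gave, in place of 111, the count in brackets for CX_DYT6KO_naive_76 (46), CX_DYT6KO_naive_63 (47), CX_wt_naive_31 (58), CX_DYT6KO_naive_135 (62), CX_wt_naive_67 (64), CX_wt_naive_96 (66), CX_wt_naive_124 (69) and CX_DYT6KO_naive_18 (216). A fit on these 2 groups alone called 0 by edgeR (150 at an unadjusted p under 0.05), and DESeq2 on all 4 groups 24.95% of its tested miRNAs. Without both CX_DYT6KO_naive_16 and CX_DYT6KO_naive_18, an alternative chosen after seeing the data, 225 were called, all 111 among them. On the second principal component CX_DYT6KO_naive_16, CX_DYT6KO_naive_63, CX_wt_naive_118 and CX_wt_naive_124 lay apart (-16.4, -7.79, -10.0 and -10.6, other cortex libraries -0.548 to 5.31). miR-3099-3p, which had 0 counts in these 4, took 50.1% of the squared weights of that component. Without it and the other miRNAs with such counts of 0, chosen after seeing the data, only CX_DYT6KO_naive_16 of these lay apart (14.96, other cortex libraries -8.15 to 3.71). The split between directions was 80 higher and 18 lower without let-7 and miR-98, and 69 higher and 16 lower with no low-count filter.

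After nerve crush, edgeR called 0 of 549 miRNAs between Thap1+/- and wild-type cortex, with 43 at an unadjusted p under 0.05, and DESeq2 also called 0. The 5 smallest p among miRNAs of at least 10 CPM belonged to miR-145a-3p (-0.41 ± 0.12, adjusted p = 0.472), miR-149-5p (-0.46 ± 0.16), miR-20a-5p (0.24 ± 0.09), miR-136-5p (-0.66 ± 0.25) and miR-16-5p (0.20 ± 0.08), none of which passed. All 9 let-7 and miR-98 members had positive fold changes with a median of 0.18, and camera called the set higher (camera adjusted p = 7.32e-05; adjusted p = 0.987 with an estimated correlation), although no member passed. Averaged over naive and crushed mice, the genotype effect had 0 calls by edgeR (86 unadjusted) and 7 by DESeq2. miR-341-3p came closest (0.36 ± 0.10, adjusted p = 0.113), followed by miR-499-5p (0.31 ± 0.09), which is encoded in a myosin gene. Without CX_DYT6KO_naive_18 the averaged effect had 69 calls, and without CX_DYT6KO_naive_16 as well 86.

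The most calls after nerve injury were in wild-type cortex, where 192 of 549 miRNAs differed between crushed and naive mice, 116 higher and 76 lower after crush. miR-339-5p rose from 7.35 ± 2.29 to 19.1 ± 2.93 CPM (SD, n = 5 and 6), a log2 fold change of 1.37 ± 0.20 (adjusted p = 0.000315), and it was higher in 6 of 6 crushed libraries than the naive mean. miR-434-3p rose from 61.2 ± 9.33 to 157 ± 21.2 CPM (1.36 ± 0.26), miR-487b-3p from 88.4 ± 10.9 to 201 ± 28.8 CPM (1.19 ± 0.20), and miR-221-3p, which is induced in Schwann cells after nerve injury, from 521 ± 46.7 to 871 ± 56.9 CPM (0.74 ± 0.14). let-7c-5p fell from 137497 ± 6944 to 91093 ± 10482 CPM (-0.59 ± 0.11) and miR-382-5p from 5375 ± 325 to 3474 ± 186 CPM (-0.63 ± 0.11). Detected miRNAs were 637 ± 4.83 in naive and 661 ± 16.7 in crushed wild-type libraries, and 658 ± 25.3 and 652 ± 10.1 in Thap1+/-. The TMM factor was 0.880 ± 0.0313 and 1.09 ± 0.0388 in wild type, so these signs move with the wild-type naive group. For miR-339-5p, miR-487b-3p, miR-341-3p, miR-221-3p, let-7c-5p and miR-382-5p all 6 crushed libraries lay on one side of all 5 naive libraries. Leaving out any 1 library left 25.7% to 33.3% of tested miRNAs called, against 34.97% with all. With no low-count filter 110 higher and 46 lower passed, and without let-7 and miR-98 114 higher and 52 lower.

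All 9 let-7 and miR-98 members fell, let-7e-5p/7k with -0.52 ± 0.12 and let-7d-5p with -0.60 ± 0.10 (camera adjusted p = 1.81e-09; adjusted p = 0.275 with an estimated correlation). Of 17 members of the nerve injury list, 8 rose and 1 fell: miR-30b-5p rose by 1.02 ± 0.20, miR-145a-5p by 0.83 ± 0.23, miR-146a-5p by 0.65 ± 0.15 and miR-21a-5p by 0.37 ± 0.11, and miR-155-5p fell (-0.56 ± 0.14). This list moved up on balance (fry adjusted p = 0.00151) but not beyond other miRNAs (camera adjusted p = 0.358). Microglia and inflammation miRNAs did likewise, with 4 of 9 higher and 1 lower (fry adjusted p = 0.00509; camera adjusted p = 0.490), as did the neuron-enriched list with 6 of 13 higher and 1 lower (fry adjusted p = 0.0296; camera adjusted p = 0.507); miR-124-5p rose by 0.79 ± 0.16. In the Dlk1-Dio3 list 23 of 81 arms rose and 12 fell, and 25 and 13 adjusted over the list alone (fry adjusted p = 0.00151; camera adjusted p = 0.383). The mitochondrial and energy list had 7 of 21 higher, such as miR-15a-5p (0.94 ± 0.17), miR-15b-5p (0.87 ± 0.19) and miR-195a-5p (0.59 ± 0.14), and 5 lower, such as miR-16-5p (-0.41 ± 0.08) and miR-26b-5p (-0.39 ± 0.09). Its members changed in either direction (fry mixed, adjusted p = 1.13e-05) with a median of 0.02, which turned to -0.04 with relative log expression (RLE) scaling.

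Smaller lists changed in part. Astrocyte-enriched miRNAs had 3 of 7 higher (miR-29a-3p, 0.43 ± 0.13) and 2 lower (miR-26a-5p, -0.31 ± 0.08). In the oligodendrocyte list 3 of 7 rose, led by miR-23a-3p/23b-3p (0.33 ± 0.13). Muscle miRNAs had 2 of 4 higher, among them miR-499-5p (0.69 ± 0.12), and miR-1a-3p lower (-0.26 ± 0.08). In the vessel list miR-145a-5p and miR-145a-3p of 8 members rose and the endothelial miR-126a-3p fell (-0.38 ± 0.08). The dopamine and striatum list had 4 of 12 higher (miR-153-3p, 0.67 ± 0.19) and 3 lower (miR-181a-5p, -0.28 ± 0.07), and 5 and 3 adjusted over the list alone. The miR-17-92 list had 1 of 9 higher (miR-19b-3p, 1.05 ± 0.39) and 1 lower (miR-93-5p, -0.24 ± 0.08), the choroid plexus list 1 of 9 higher (miR-34b-5p, 0.84 ± 0.32), and the Sfmbt2 list 2 of 18 lower, including miR-466i-5p (-0.74 ± 0.15); adjusted over the list alone 0 of the first 2 lists and 1 of the Sfmbt2 list passed. No member of the activity-regulated list (7 members) or the red cell list (4 members) passed by edgeR in either adjustment. Apart from let-7, camera called none of these lists.

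In Thap1+/- cortex, crush was followed by 4 calls. miR-138-2-3p rose from 56.6 ± 11.3 to 79.4 ± 5.57 CPM (SD, n = 6 each; 0.49 ± 0.11, adjusted p = 0.0470; higher in 6 of 6 libraries) and miR-20a-5p of the miR-17-92 cluster rose by 0.36 ± 0.09. miR-3475-3p (-2.35 ± 0.54) and miR-7013-5p (-0.86 ± 0.20) fell, both at mean levels near 1.92 CPM. let-7c-5p, which fell in wild type, had 0.00 ± 0.10 here, and miR-339-5p -0.05 ± 0.18. Adjusted over the list alone, miR-181c-5p of the mitochondrial list, known to act on a transcript of the mitochondrial genome, was lower (-0.52 ± 0.14) and miR-499-5p higher (0.41 ± 0.12). The 4 calls became the count in brackets without CX_DYT6KO_crush_117, CX_DYT6KO_crush_46, CX_DYT6KO_crush_47, CX_DYT6KO_crush_8, CX_DYT6KO_crush_86, CX_DYT6KO_naive_135, CX_DYT6KO_naive_63 and CX_DYT6KO_naive_76 (0 each), CX_DYT6KO_crush_133 and CX_DYT6KO_naive_16 (2 each) and CX_DYT6KO_naive_18 (20). RLE scaling gave 7 (2 higher, 5 lower), DESeq2 14, no low-count filter and a fit on the 2 groups alone 0 each (91 and 38 unadjusted), and leaving out both CX_DYT6KO_naive_16 and CX_DYT6KO_naive_18 25.

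The difference between the crush effects of the genotypes was tested directly, and 74 miRNAs passed, 31 with a higher and 43 with a lower effect in Thap1+/- cortex. This test also includes the wild-type naive libraries, whose let-7 share was the highest (55.2%, other cortex groups 45.9% to 48.7%). Among the other cortex groups edgeR called 0 for genotype after crush (43 unadjusted) and 4 for crush in Thap1+/- (47 unadjusted). The wild-type naive group alone could thus give rise to the 74, and a genotype-dependent response to injury is not shown. The difference was -1.42 ± 0.27 for miR-339-5p (adjusted p = 0.00640), -1.50 ± 0.35 for miR-434-3p, -1.11 ± 0.28 for miR-487b-3p and -0.79 ± 0.20 for miR-341-3p. It was positive for let-7c-5p (0.60 ± 0.15), miR-382-5p (0.72 ± 0.15) and miR-16-5p (0.51 ± 0.11). All 9 let-7 and miR-98 members passed with positive differences (camera adjusted p = 1.46e-07; adjusted p = 0.520 with an estimated correlation). Averaged over genotypes, crush was followed by 91 calls, 59 higher and 32 lower, or 41 higher and 51 lower with RLE scaling. This average also includes the wild-type naive libraries. Crush had 192 calls in wild type and 4 in Thap1+/-, so the 91 do not show a response shared by both genotypes. miR-499-5p (0.55 ± 0.09), miR-186-5p (0.36 ± 0.06) and miR-221-3p (0.53 ± 0.10) led those that rose, and miR-181d-5p (-0.36 ± 0.06), miR-383-5p (-0.45 ± 0.08) and miR-181a-5p (-0.25 ± 0.05) those that fell. The interaction calls, 13.5% of tested miRNAs, became the percentage in brackets without CX_DYT6KO_naive_76 (7.89%), CX_DYT6KO_crush_86 (8.24%), CX_DYT6KO_naive_63 (9.02%), CX_DYT6KO_naive_16 (20.7%) and CX_DYT6KO_naive_18 (33.2%). Their number was 207 without both CX_DYT6KO_naive_16 and CX_DYT6KO_naive_18, 48 with no filter and 113 with DESeq2. Without let-7 and miR-98 the difference was positive for 13 and negative for 50. The averaged crush effect had 59 calls without CX_DYT6KO_crush_8. Its split was 48 higher and 14 lower with no filter, 52 higher and 49 lower with a stricter one and 54 higher and 66 lower with DESeq2. Without let-7 and miR-98 it was 62 higher and 25 lower.

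The genotype effect in naive mice and the crush effect in wild type are both measured against the same 5 wild-type naive libraries. Across miRNAs (which are not independent replicates) their fold changes had a Pearson r of 0.890 and a covariance of 0.391, and 105 miRNAs were called in both in the same direction. Unchanged groups simulated against shared controls gave r = 0.572 and a covariance of 0.121, and independent lists of these sizes would share 20.5. With the controls split between the comparisons, over 10 splits the mean r was 0.498 (range 0.336 to 0.597), the covariance 0.344 and the shared calls 9.10.

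**Figure D2:**
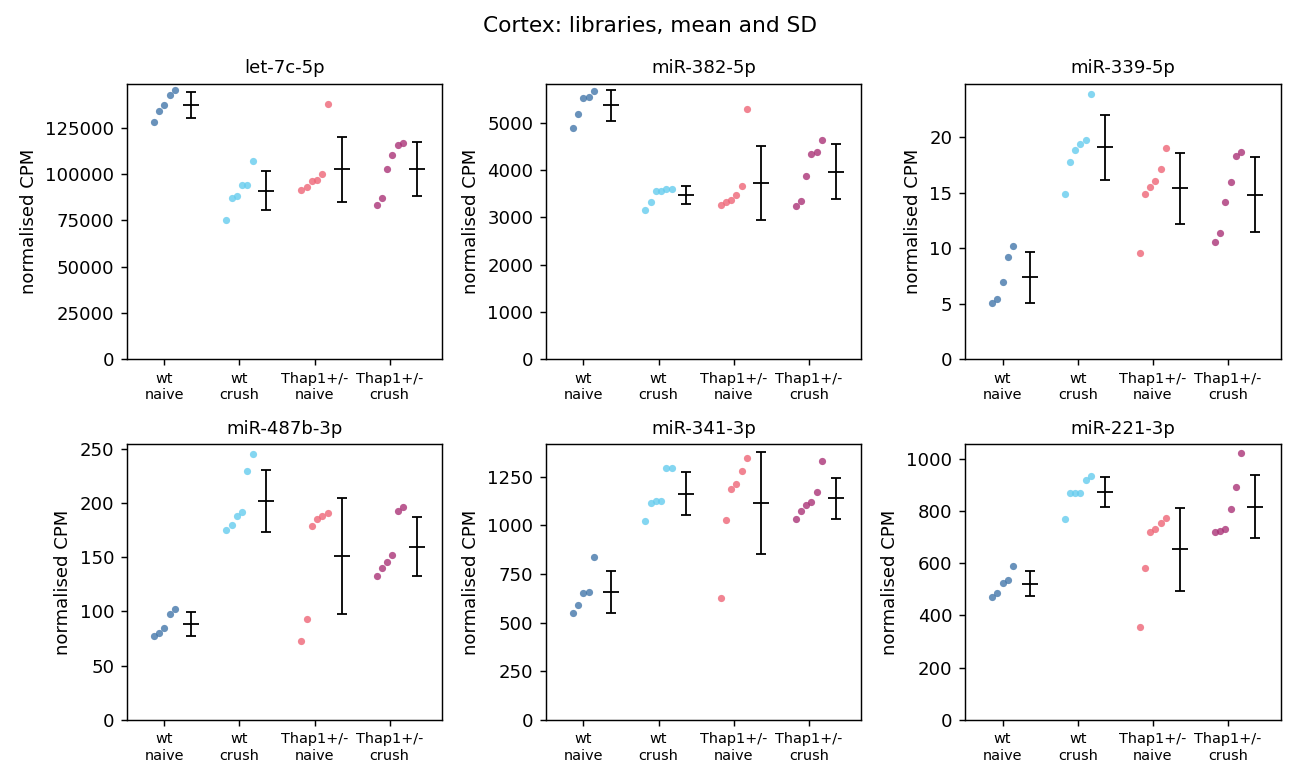
Normalised CPM of 6 miRNAs in each cortex library, by group, with the mean and SD beside the points. The wild-type naive libraries lie at 5.02 to 10.2 CPM for miR-339-5p and the wild-type crushed ones at 14.9 to 23.9, while 1 naive Thap1+/- library lies among the wild-type naive ones for let-7c-5p and miR-382-5p.

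In striatum, miR-221-3p was lower after crush in both genotypes. Its level was 949 ± 145.5 CPM in naive and 680.3 ± 42.1 CPM in crushed wild-type mice, and 752 ± 121 and 558 ± 74.7 CPM in Thap1+/- mice (SD, n = 6 each). Averaged over genotypes it fell by 0.45 ± 0.08 (adjusted p = 0.00401), where in cortex it rose, and the difference between the regions in this effect was -0.98 ± 0.13 (adjusted p = 1.57e-07). In all 9 miRNAs fell and 0 rose with crush on average: miR-221-3p, miR-384-5p (-0.30 ± 0.06), miR-30b-5p (-0.34 ± 0.07), miR-30c-5p (-0.27 ± 0.06), miR-195a-5p (-0.27 ± 0.06), miR-15b-5p (-0.27 ± 0.06), miR-186-5p (-0.24 ± 0.06), miR-434-3p (-0.38 ± 0.10) and miR-411-3p (-0.24 ± 0.06). miR-195a-5p and miR-15b-5p belong to the miR-15/16 family of cell cycle regulators. This count became the value in brackets without STR_wt_crush_11, STR_wt_naive_124 and STR_wt_naive_96 (1 each), STR_DYT6KO_crush_117, STR_DYT6KO_crush_133, STR_wt_crush_113 and STR_wt_crush_139 (2 each), STR_wt_naive_118 (4) and STR_DYT6KO_crush_8 (18). It was 2 with RLE scaling, 3 with no filter, 24 with DESeq2 (8 higher, 16 lower) and 18 without STR_DYT6KO_crush_8, which stood apart on the first principal component (-28.8, others of the group -1.70 to 5.16). Detected miRNAs went from 702 ± 8.80 in naive to 681 ± 16.1 in crushed wild-type libraries and from 676 ± 9.35 to 659.7 ± 19.002 in Thap1+/- (mean ± SD, n = 6 each), and mean totals from 11204200 ± 458012 to 9930700 ± 589624 and from 9534070 ± 1289530 to 9361520 ± 671656 counts. These signs of library quality move with crush, the totals in wild type only, and their part in the calls was not tested.

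Within single groups little passed in striatum. In wild type 1 miRNA, miR-411-3p of the Dlk1-Dio3 locus, fell after crush, from 40.4 ± 4.68 to 30.2 ± 2.55 CPM (-0.42 ± 0.09, adjusted p = 0.0399; lower in 6 of 6 libraries), and miR-221-3p did not pass (-0.48 ± 0.11, adjusted p = 0.0767). The miR-411-3p call was lost by edgeR with RLE scaling, with no filter, with a stricter filter and with the 2 groups alone (31, 77, 24 and 55 unadjusted), DESeq2 called 2, and the count changed without STR_wt_crush_11, STR_wt_crush_113, STR_wt_crush_139, STR_wt_crush_14, STR_wt_crush_2, STR_wt_naive_118, STR_wt_naive_124, STR_wt_naive_67 and STR_wt_naive_96 (0 each), STR_wt_naive_136 (2) and STR_wt_crush_3 (3). edgeR called 0 miRNAs for crush in Thap1+/- (47 unadjusted, 12 by DESeq2; 2 each without STR_DYT6KO_crush_8 or STR_DYT6KO_naive_63), 0 for genotype in naive mice (25 unadjusted, 0 by DESeq2), 0 for genotype after crush (33 unadjusted, 1 by DESeq2), 0 for the averaged genotype effect (36 unadjusted, 1 by DESeq2; 1 without STR_DYT6KO_naive_18) and 0 for the interaction (21 unadjusted, 0 by DESeq2). The smallest p belonged to miR-195a-5p for crush in Thap1+/- (-0.37 ± 0.09), miR-3473b/3473e for genotype in naive mice (0.45 ± 0.14) and miR-344-3p both for genotype after crush (0.62 ± 0.19) and for the interaction (0.86 ± 0.27). Adjusted over the list alone, miR-221-3p and miR-30b-5p of the nerve injury list were lower after crush in both genotypes, and miR-195a-5p and miR-15b-5p of the mitochondrial list in Thap1+/- mice. The let-7 family had 5 of 9 higher after crush in Thap1+/- adjusted over the list alone, among them let-7f-5p (0.29 ± 0.09) and let-7i-5p (0.28 ± 0.09), and 0 over all miRNAs (camera adjusted p = 0.000259; adjusted p = 0.301 with an estimated correlation). Astrocyte-enriched miRNAs, with miR-449a-5p (0.38 ± 0.12) and miR-31-5p (0.23 ± 0.08) higher adjusted over the list alone, had a camera call in the same comparison (camera adjusted p = 0.00390; adjusted p = 0.301 with an estimated correlation). Without STR_DYT6KO_crush_8 camera called 1 list there in place of 2.

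**Figure D3:**
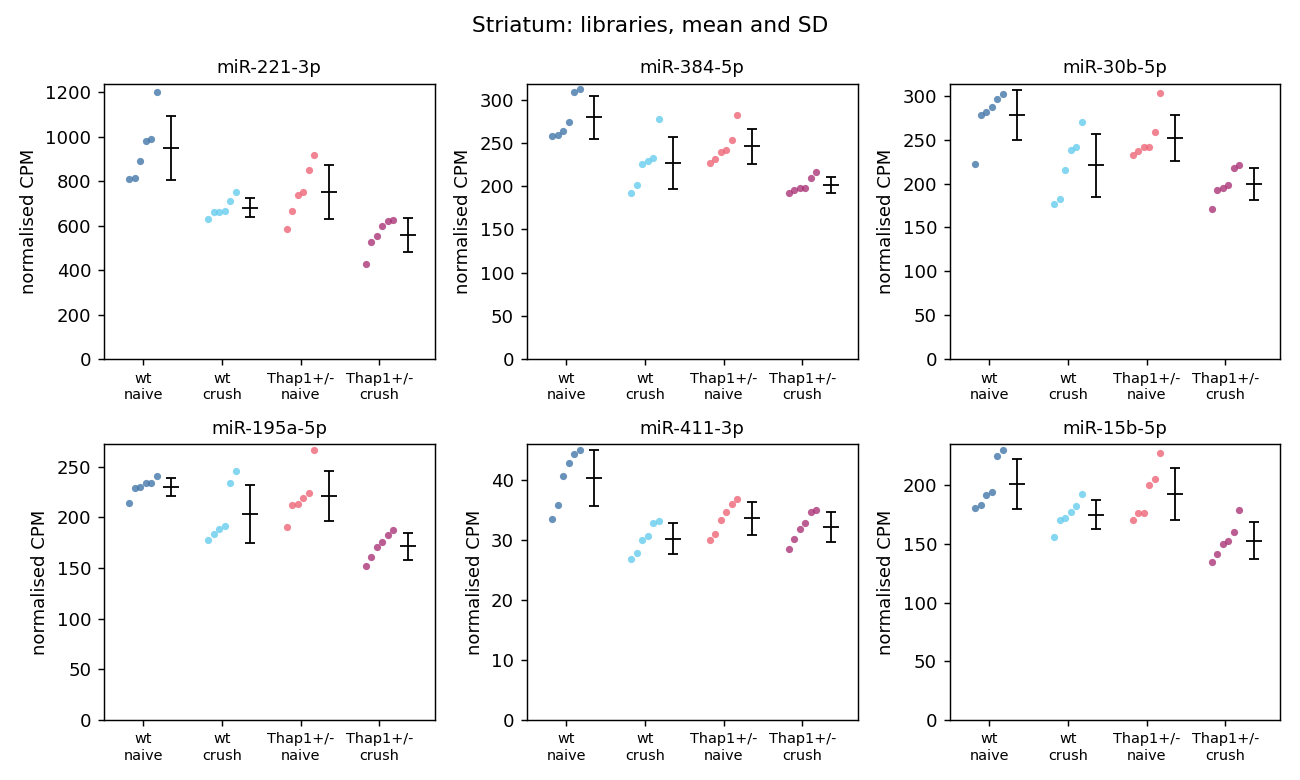
Normalised CPM of 6 miRNAs in each striatum library, by group, with the mean and SD beside the points. miR-221-3p averages 949 CPM in wild-type naive and 558 CPM in crushed Thap1+/- libraries, with overlapping points between neighbouring groups.

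In cerebellum the genotypes differed after nerve crush. There 74 of 552 miRNAs passed, 24 higher and 50 lower in Thap1+/-; with RLE scaling 26 were higher and 26 lower. miR-30c-5p fell from 397 ± 53.1 CPM in crushed wild type to 243 ± 34.97 CPM in crushed Thap1+/- cerebellum (SD, n = 6 each; -0.71 ± 0.09, adjusted p = 2.63e-05), with all 6 Thap1+/- libraries below all 6 of wild type. miR-30b-5p (-0.70 ± 0.14), miR-30a-5p (-0.44 ± 0.10) and miR-30e-5p (-0.44 ± 0.10) fell too. miR-9-3p, from a hairpin known for its role in neurogenesis, fell from 19779 ± 2141 to 14653 ± 1326 CPM (-0.43 ± 0.08), its other arm miR-9-5p changed by -0.44 ± 0.09, and miR-340-5p by -0.46 ± 0.08. Among those that rose, miR-770-3p went from 40.8 ± 4.52 to 64.9 ± 14.4 CPM (0.67 ± 0.14), miR-505-5p changed by 0.79 ± 0.19, miR-669c-5p by 0.54 ± 0.13 and let-7b-5p by 0.49 ± 0.14. Mir770 lies at chromosome 12, 109563692 to 109563785 (GRCm38) inside the noncoding gene Meg3, and Mir340 at chromosome 11, 50069702 to 50069799 inside Rnf130.

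Neuron-enriched miRNAs had 4 of 13 lower, miR-9-5p, miR-9-3p, miR-218-5p (-0.42 ± 0.08) and miR-124-5p (-0.50 ± 0.16), the same number adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.393 with an estimated correlation). The let-7 family had 2 of 9 higher, let-7b-5p and miR-98-5p (0.55 ± 0.18), and 6 adjusted over the list alone (camera adjusted p = 0.00139; adjusted p = 0.480 with an estimated correlation). The Sfmbt2 list had 2 of 23 higher, miR-669c-5p and miR-466i-5p (0.85 ± 0.28), and 1 adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.480 with an estimated correlation). Without both CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86, chosen after seeing the data, camera called 0 lists in this comparison in place of 3. These shifts of lists are thus not shown for the group without those libraries. In the Dlk1-Dio3 list 5 of 76 rose and 11 fell, and 6 and 13 adjusted over the list alone (fry adjusted p = 0.0245; camera adjusted p = 0.272). Astrocyte-enriched miR-29a-3p (-0.45 ± 0.10) and miR-29c-3p (-0.47 ± 0.14) fell. In the vessel list the endothelial miR-126a-5p (-0.41 ± 0.08) fell, as did miR-145a-5p (-0.65 ± 0.18). miR-29a-3p was the only one of 21 members of the mitochondrial list to pass, and the list was lower on balance (fry adjusted p = 0.000814; camera adjusted p = 0.170). The nerve injury list had 2 of 18 lower (miR-30b-5p and miR-145a-5p), and 3 adjusted over the list alone. The dopamine list had 2 of 12 lower (miR-212-3p, -0.59 ± 0.16, and miR-382-3p, -0.62 ± 0.15), and 5 lower and 1 higher adjusted over the list alone. The red cell list had 1 of 4 higher. No member of the Hox list (4 members) or of the miR-183 cluster (3 members) passed by edgeR in either adjustment. In the choroid plexus list miR-204-3p rose (0.57 ± 0.18) and miR-141-3p (-3.23 ± 1.07) and miR-200c-3p (-3.41 ± 1.10) fell. CB_wt_crush_3 alone held 346 CPM of miR-200c-3p and 393 CPM of miR-141-3p, and without it their fold changes were 0.34 and 0.20. CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86 also stood apart: let-7 and miR-98 took 75.7% and 74.2% of their counts (the others of the group 61.2 to 67.5%), and they had 586 and 593 detected miRNAs (others 628 to 662). CB_DYT6KO_crush_46 lay between these 2 and the rest on the first principal component (9.35, against 19.5 and 17.1, and -1.92 to 1.93 in the others), but its let-7 share was the lowest of the group. These 3 libraries are those with 0 counts of miR-337-3p, and without the miRNAs with such counts of 0 the score of CB_DYT6KO_crush_46 was 5.88, against 17.3 and 15.6. The signs of CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86 go with the higher let-7 levels and the lower levels of other miRNAs in this group. The count of 74 became the value in brackets without CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86 (21 each), CB_wt_crush_3 (32), CB_wt_crush_2 (38) and CB_wt_crush_11 (43), and 10 without both CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86. It was 31 with no filter, 6 with the 2 groups alone and 46 (23 higher, 23 lower) without let-7 and miR-98. Replicates differed most in crushed Thap1+/- cerebellum (median chi-square per degree of freedom 645, other cerebellum groups 86.3 to 279). A spread shared by 4 groups may be too small for that group. The split was 30 higher and 25 lower with a stricter filter and 40 higher and 45 lower with DESeq2.

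Crush in Thap1+/- cerebellum was followed by 29 calls, 7 higher and 22 lower, or 20 higher and 18 lower with RLE scaling. miR-30c-5p fell from 384 ± 12.4 to 243 ± 34.97 CPM (SD, n = 6 each; -0.66 ± 0.09, adjusted p = 9.43e-05; lower in 6 of 6 libraries), miR-340-5p changed by -0.50 ± 0.08, miR-126a-5p by -0.44 ± 0.08 and miR-191-5p by -0.38 ± 0.09. let-7c-5p rose from 141573 ± 16288 to 204127 ± 63262 CPM (0.53 ± 0.16) and miR-98-5p rose by 0.72 ± 0.18. The let-7 list had 2 of 9 higher and 9 adjusted over the list alone (camera adjusted p = 4.87e-06; adjusted p = 0.463 with an estimated correlation), the Sfmbt2 list 1 of 23 and 6 adjusted over the list alone (camera adjusted p = 0.000182; adjusted p = 0.296 with an estimated correlation), and the neuron-enriched list 3 of 13 lower, and 6 lower with 2 higher adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.463 with an estimated correlation). The count moved without CB_DYT6KO_crush_47 (6), CB_DYT6KO_naive_135 (7), CB_DYT6KO_naive_18 (8), CB_DYT6KO_crush_86 and CB_DYT6KO_naive_76 (10 each), CB_DYT6KO_naive_16 (14), CB_DYT6KO_naive_63 (19), CB_DYT6KO_crush_46 (45), CB_DYT6KO_crush_133 (75) and CB_DYT6KO_crush_117 (76), and was 4 without both CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86, 11 with no filter, 70 with DESeq2 (43 higher, 27 lower) and 8 with the 2 groups alone. The split was 12 higher and 14 lower without let-7 and miR-98, and 20 higher and 20 lower with a stricter filter. Without both CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86 camera called 2 lists in place of 3. This comparison and the genotype comparison after crush share the crushed Thap1+/- libraries: their fold changes across miRNAs had r = 0.615 (covariance 0.136) with 23 calls in both, against r = 0.506 (covariance 0.141) for simulated unchanged groups and 2.30 calls for independent lists. Over 20 splits of the shared libraries the mean r was 0.0797 (range -0.154 to 0.271), the covariance 0.0268 and the shared calls 5.45.

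In naive cerebellum edgeR called 0 miRNAs between genotypes (50 unadjusted, 0 by DESeq2, 5 in a fit on the 2 groups alone, and 1 without CB_DYT6KO_naive_76). miR-142a-3p, a marker of blood-derived and microglial cells, came closest with let-7a-1-3p/7c-2-3p (-0.61 ± 0.17 and -0.58 ± 0.16, adjusted p = 0.252 for both). For crush in wild type edgeR called 0 (44 unadjusted, 0 by DESeq2). Here 4 of 12 choroid plexus and ependyma miRNAs were higher adjusted over the list alone, miR-141-3p (3.19 ± 1.06), miR-200c-3p (3.62 ± 1.10), miR-200a-3p (2.22 ± 0.83) and miR-429-3p (2.08 ± 0.74), epithelial miRNAs of the miR-200 family (camera adjusted p = 0.0167; adjusted p = 0.835 with an estimated correlation). All 4 changed sign without CB_wt_crush_3, to -0.23, -0.13, -0.40 and -0.09. The let-7 family was higher as a set (camera adjusted p = 0.00105; adjusted p = 0.835 with an estimated correlation) and the list of microglia and inflammation lower (camera adjusted p = 0.0140; adjusted p = 0.344 with an estimated correlation), with no member passing in either. The interaction had 0 calls by edgeR (57 unadjusted, 1 by DESeq2, and 1 each without CB_DYT6KO_crush_133, CB_DYT6KO_crush_8 or CB_wt_crush_11), so a difference in crush effect between genotypes was not shown; miR-30c-5p came closest (-0.58 ± 0.13, adjusted p = 0.0726).

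Averaged over naive and crushed mice, 72 miRNAs differed by genotype in cerebellum, 26 higher and 46 lower in Thap1+/-. miR-30c-5p (-0.42 ± 0.06), miR-340-5p (-0.32 ± 0.06), miR-218-5p (-0.28 ± 0.05) and miR-29c-3p (-0.42 ± 0.10) fell, and miR-676-3p (0.39 ± 0.09), miR-342-5p (0.52 ± 0.12) and miR-877-5p (0.65 ± 0.17) rose. That count became the value in brackets without CB_DYT6KO_naive_48 (35), CB_DYT6KO_naive_63 (38), CB_DYT6KO_crush_47 (39), CB_DYT6KO_crush_86 (41), CB_wt_naive_124 (46), CB_DYT6KO_crush_133 (112) and CB_DYT6KO_crush_117 (123), 20 without both CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86, and 40 with no filter. A stricter filter gave 31 higher and 26 lower, and the fit without let-7 and miR-98 25 higher and 32 lower. Averaged over genotypes, 18 differed with crush, 6 higher and 12 lower (9 and 11 with RLE scaling). let-7c-5p (0.40 ± 0.11), let-7d-5p (0.34 ± 0.09) and miR-98-5p (0.48 ± 0.13) rose, and miR-340-5p (-0.36 ± 0.06), miR-30c-5p (-0.37 ± 0.06) and miR-384-5p (-0.35 ± 0.08) fell. This count moved without CB_DYT6KO_naive_135 (8), CB_DYT6KO_crush_47, CB_DYT6KO_naive_18, CB_DYT6KO_naive_76, CB_wt_crush_113, CB_wt_crush_14, CB_wt_naive_118, CB_wt_naive_124 and CB_wt_naive_136 (10 each), CB_DYT6KO_crush_86, CB_DYT6KO_naive_16 and CB_wt_naive_96 (11 each), CB_wt_crush_2 (32), CB_DYT6KO_crush_46 (36), CB_DYT6KO_crush_133 (55) and CB_DYT6KO_crush_117 (64), and to 9 with no filter (0 higher and 9 lower), 31 with a stricter one (14 higher and 17 lower), 60 with DESeq2 (34 higher and 26 lower), 10 without let-7 and miR-98 (0 higher and 10 lower) and 8 without both CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86.

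**Figure D4:**
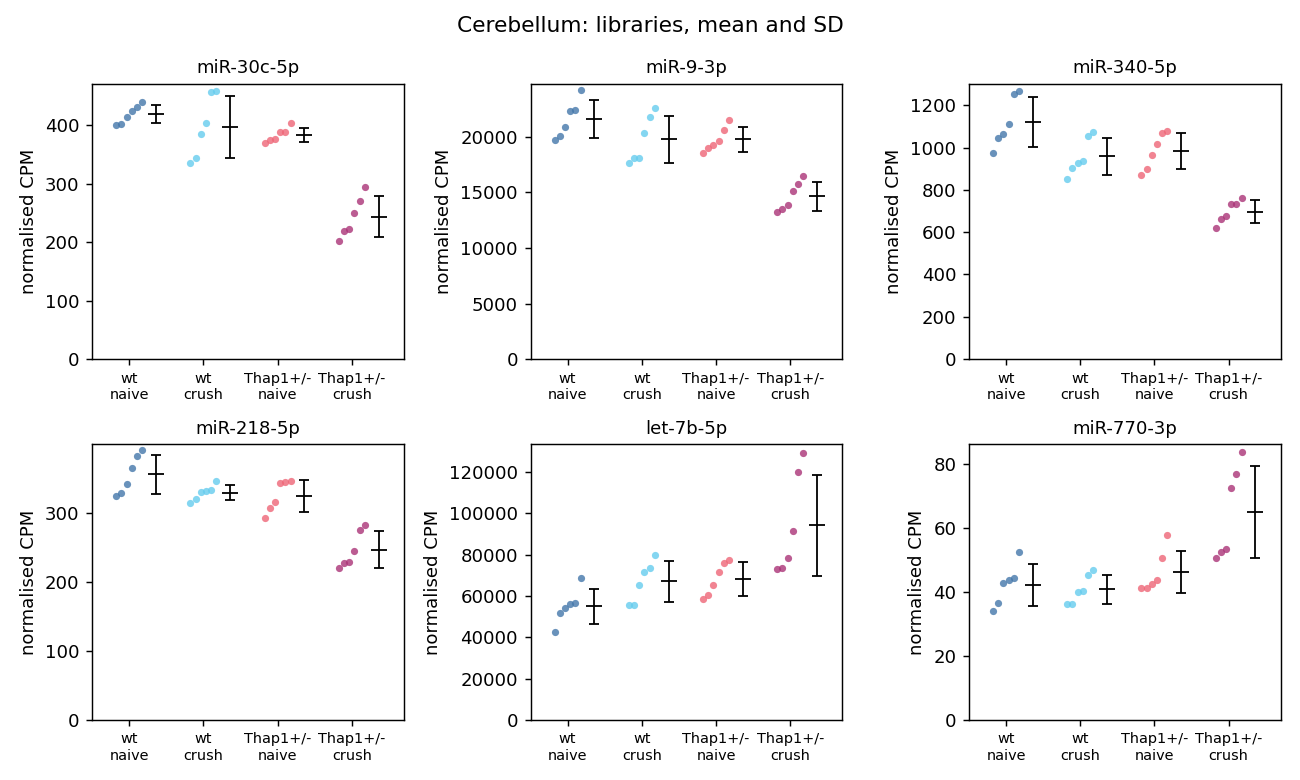
Normalised CPM of 6 miRNAs in each cerebellum library, by group, with the mean and SD beside the points. The crushed Thap1+/- libraries lie at 201 to 294 CPM for miR-30c-5p, below all 6 crushed wild-type libraries (336 to 458 CPM).

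More miRNAs differed between the regions than between groups within any region. In naive wild-type mice 316 of 579 miRNAs differed between striatum and cortex (207 higher and 109 lower in striatum), 397 between cerebellum and cortex (216 higher in cerebellum and the others lower) and 396 between cerebellum and striatum (180 and 216). miR-187-3p was at 5034 ± 339.8 CPM in striatum (SD, n = 6) against 217 ± 60.5 in cortex (n = 5), a log2 fold change of 4.53 ± 0.14 (adjusted p = 1.38e-14). miR-139-5p, encoded in an intron of Pde2a, was highest in striatum at 23572 ± 1866 CPM and lowest in cerebellum at 703 ± 89.8 CPM (n = 6; -5.07 ± 0.11 between them). miR-34a-5p, a p53 target, was lower in striatum than in cortex (-2.40 ± 0.14), and miR-7a-5p, which represses alpha-synuclein, was higher (1.85 ± 0.14). Cerebellum stood out by miR-206-3p, known for its role at the neuromuscular junction, at 3051 ± 594 CPM against 26.9 ± 7.02 in cortex (6.83 ± 0.23), by miR-195a-5p (2.91 ± 0.10) and by miR-10a-5p, encoded in a Hox cluster, at 328 ± 178 CPM against 8.88 ± 2.67 (5.20 ± 0.45). The activity-dependent miR-132-3p was at 90.3 ± 9.60 CPM in cerebellum and 661 ± 116 CPM in cortex (-2.87 ± 0.11). miR-3099-3p had 0 counts in all 6 cerebellum libraries, but also in 2 of the 5 cortex libraries, whose others reached 657 CPM, so its 0 in cerebellum is not read as a difference between regions.

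In the Dlk1-Dio3 list 51 of 79 arms were higher and 3 lower in striatum than in cortex (camera adjusted p = 0.000161; adjusted p = 0.498 with an estimated correlation), 14 higher and 43 lower in cerebellum than in cortex (camera adjusted p = 0.00646; adjusted p = 0.303 with an estimated correlation), and 2 higher and 65 lower in cerebellum than in striatum (camera adjusted p = 9.31e-08; adjusted p = 0.0692 with an estimated correlation). All 8 vessel miRNAs were lower in striatum than in cortex (camera adjusted p = 0.00270; adjusted p = 0.498 with an estimated correlation), as were all 9 of the let-7 family (camera adjusted p = 0.000161; adjusted p = 0.706 with an estimated correlation). In cerebellum against cortex, 20 of 22 Sfmbt2 arms were higher and 1 lower (camera adjusted p = 0.00117; adjusted p = 0.303 with an estimated correlation), as were 5 of 5 muscle miRNAs (camera adjusted p = 0.00646; adjusted p = 0.0937 with an estimated correlation), 3 of 3 in the miR-183 cluster, known from sensory organs (camera adjusted p = 0.0211; adjusted p = 0.303 with an estimated correlation), 3 of 3 Hox miRNAs (camera adjusted p = 0.0271; adjusted p = 0.303 with an estimated correlation) and 7 of 10 choroid plexus miRNAs (camera adjusted p = 0.0211; adjusted p = 0.360 with an estimated correlation). The mitochondrial list had 12 of 21 higher and 4 lower there (camera adjusted p = 0.0435; adjusted p = 0.303 with an estimated correlation), and the activity-regulated list 2 of 7 higher and 5 lower (camera adjusted p = 0.00646; adjusted p = 0.303 with an estimated correlation). In each of these the same numbers passed adjusted over the list alone, except 52 higher for Dlk1-Dio3 in striatum against cortex and 3 higher in cerebellum against striatum. Between cerebellum and striatum, vessel (adjusted p = 0.216 with an estimated correlation), let-7 (adjusted p = 0.476 with an estimated correlation), muscle (adjusted p = 0.0692 with an estimated correlation), Hox (adjusted p = 0.225 with an estimated correlation), miR-183 (adjusted p = 0.216 with an estimated correlation), mitochondrial (adjusted p = 0.216 with an estimated correlation) and Sfmbt2 miRNAs (adjusted p = 0.292 with an estimated correlation) were higher in cerebellum and activity-regulated ones (adjusted p = 0.267 with an estimated correlation) lower by camera with its preset correlation. RLE scaling moved the median of all miRNAs by -0.16 for striatum against cortex, from 0.19, and turned its split to 158 higher and 147 lower (DESeq2 159 higher and 150 lower); for cerebellum against striatum the shift was 0.11. Cerebellum RNA was extracted with another kit than the other regions, so its differences from them and those of the kits cannot be told apart. A stricter filter on low counts left 254 calls for cerebellum against cortex.

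**Figure D5:**
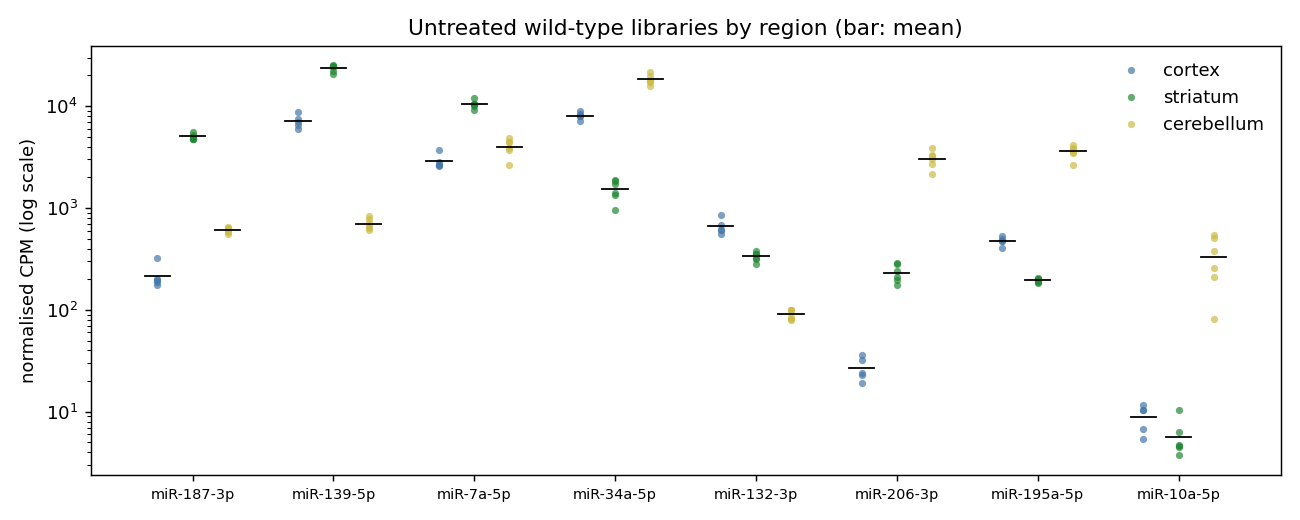
Normalised CPM (log axis) of 8 miRNAs in each naive wild-type library, coloured by region, with a bar at the mean of each region. miR-206-3p averages 26.9 CPM in cortex, 232 in striatum and 3051 in cerebellum, and the libraries of the 3 regions do not overlap for it.

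The authors' deposited tables give their own adjusted p for the same comparisons within regions. For crush in wild-type cortex, 175 miRNAs passed in the authors' deposited table, 169 of them among the 192 called here. For genotype in naive cortex, 109 of the 111 called here also passed in the authors' deposited table. For genotype after crush in cerebellum, the authors' deposited table had 80, of which 66 were called here, and for crush in Thap1+/- cerebellum 65, of which 27 were called here. Crush in Thap1+/- gave 12 in cortex (4 called here) and 12 in striatum (0 called here), and crush in wild-type striatum 2 (1 called here), by the authors' deposited tables. Every miRNA called in both had the same direction. Over the miRNAs tested here, called or not, the authors' log2 fold changes and those here were less alike. Their Pearson r ran from 0.441 for genotype after crush in cortex to 0.818 for genotype after crush in cerebellum. It was 0.706 for genotype in naive cortex and 0.726 for crush in wild-type cortex, and the cause was not tested. The authors' deposited tables held 0 for the other 5 comparisons within regions, for which edgeR called 0 here as well (43 unadjusted for genotype after crush in cortex, 25 and 33 for genotype in striatum before and after crush, 50 for genotype in naive cerebellum and 44 for crush in wild-type cerebellum, and by DESeq2 0, 0, 1, 0 and 0).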

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

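The comparisons of effects between regions and the tests without let-7 and miR-98, without the libraries that stand apart in each region, of sampling depth, of principal components and of hairpin arms were chosen only after the results they concern had been seen. The main design, the named-miRNA rule, the lists and the alternatives not named here or said elsewhere to be chosen later were fixed before the data were examined.

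Effects were compared between regions and genotypes by tests of the difference itself. In cortex 13.5% of the miRNAs tested passed the test of genotype by crush. The averaged crush effect differed between striatum and cortex for 13.1% of 655 miRNAs (25 higher and 61 lower in striatum), and between cerebellum and cortex for 23.5% (63 higher and 91 lower in cerebellum). miR-487b-3p, which rose after crush in wild-type cortex, had differences of -0.77 ± 0.19 (adjusted p = 0.00481) and -0.96 ± 0.20 (adjusted p = 0.000226), and let-7c-5p had 0.35 ± 0.11 (adjusted p = 0.0221) and 0.67 ± 0.11 (adjusted p = 1.33e-05). Between cerebellum and striatum edgeR called 0 differences of the crush effect (36 unadjusted, DESeq2 not run on these). The averaged genotype effect differed between cerebellum and cortex for 19.1% (47 higher and 78 lower in cerebellum), including miR-30c-5p (-0.60 ± 0.13, adjusted p = 0.00161). Between cerebellum and striatum it differed for 0.611%, namely let-7a-1-3p/7c-2-3p (-0.90 ± 0.18), miR-1306-3p (6.40 ± 1.61), miR-6540-3p (-0.77 ± 0.16) and miR-760-5p (6.54 ± 1.62), which were chosen after their values were seen. Between striatum and cortex edgeR called 0 (56 unadjusted, DESeq2 not run). With the library number as a replicate block over the regions, 0.305% passed for the genotype effect between cerebellum and striatum, without miR-1306-3p and miR-760-5p. Every cortex effect compared here includes the wild-type naive libraries, which had a high let-7 share and low TMM factors. What sets that group apart can therefore enter the differences from cortex.

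Single libraries lay far from the rest of their group in 10.8% of the groups of values examined (21 groups), where chance gives about 1 in 20. In cortex, CX_DYT6KO_naive_18 held 56.1% let-7 and miR-98 (others 46.1 to 49.6%), with let-7c-5p at 138139 CPM (others 91504 to 100074) and miR-382-5p at 5308 CPM (others 3270.3 to 3674). CX_wt_naive_31 had miR-30a-3p at 2581 CPM (others 2791 to 2861), miR-187-3p at 324 CPM (others 177 to 198.97) and miR-7a-5p at 3743 CPM (others 2567 to 2848). miR-20a-5p was at 118 CPM (others 102 to 104) in CX_DYT6KO_naive_63 and at 87.8 CPM (others 114 to 125) in CX_wt_crush_2, and miR-29a-3p at 39597 CPM (others 31706 to 33912) in CX_wt_crush_139. In striatum, STR_DYT6KO_naive_63 had a TMM factor of 1.14 (others 0.972 to 1.02) and miR-30b-5p at 303 CPM (others 232 to 259). STR_wt_naive_31 had miR-30b-5p at 222.8 CPM (others 279 to 303) and miR-3099-3p at 1131 CPM (others 821 to 923). In cerebellum, miR-9-5p was at 24644 CPM (others 28314 to 30411) in CB_DYT6KO_naive_48 and miR-669c-5p at 81.2 CPM (others 71.7 to 74.9) in CB_DYT6KO_naive_63. Epithelial miRNAs were high in CB_wt_crush_3, with miR-375-3p at 1446 CPM (others 11.5 to 51.6), miR-200c-3p at 346 CPM (others 1.32 to 6.58) and miR-141-3p at 393 CPM (others 3.73 to 10.7). In CB_DYT6KO_naive_135 they were at 115 CPM (others 16.01 to 41.7), 24.98 CPM (others 2.14 to 5.89) and 23.4 CPM (others 2.40 to 6.54).

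In cortex, 105 of the calls for genotype in naive mice and for crush in wild type were shared, and both comparisons use the 5 wild-type naive libraries, which had fewer detected miRNAs (637 on average, 652 to 661 in the other cortex groups) and low TMM factors (0.838 to 0.924, other cortex libraries 0.901 to 1.13). The high let-7 share of those libraries was not the whole cause, as 166 miRNAs passed for crush in wild type without let-7 and miR-98. Another fit took as a covariate each library's score on the main axis of variation within striatum groups. In it 217 passed for crush in wild type, 191 of them among the first 192, and 82 for genotype, 70 of them among the first 111. The median log2 change of those 111 went from 0.524 to 0.398, and its median standard error from 0.158 to 0.134. On the first principal component of striatum STR_DYT6KO_crush_8 lay far out (-28.8, others -3.15 to 7.11), so this axis may carry mainly that library. The fit therefore cannot exclude variation between libraries in general. After a correction for the GC content of the hairpin arm, known for 97.4% of miRNAs, 187 passed for crush in wild type, 168 of them among the first 192, and 97 for genotype, 83 of them among the first 111. Open remain a technical difference behind these signs, a state of the uninjured wild-type cortex itself and an unrecorded batch that follows this group, which the labels cannot separate, while why CX_DYT6KO_naive_18 lay with the wild-type naive libraries, and whether a label among these libraries is wrong, were not tested further.

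In cerebellum, the calls for genotype after crush rested in part on CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86: 10 miRNAs passed without both, against 17 to 170 without any of the 14 other pairs of that group. The GC content of the hairpin arm was not the whole cause (56 passed after correction, 53 of them among the first 74). With the main axis of variation within wild-type cerebellum groups as a covariate 65 passed, 59 of them among the first 74. Wild-type libraries spread more on the second principal component (-11.3 to 12.1) than on the first (-6.54 to -0.0137), where CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86 stood out (19.5 and 17.1). An axis from wild-type libraries need not carry their deviation, so this covariate cannot exclude variation between libraries. These 2 libraries had fewer detected miRNAs and a higher let-7 share than the rest of their group, so a technical difference stays open, as does a reaction to crush that is stronger in some Thap1+/- mice.

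Counts of exactly 0 appeared in some libraries for miRNAs abundant in most of their region: 14 cases of 6 miRNAs in 10 libraries, with a median count of at least 50 over the region's other libraries. miR-3099-3p had 0 in 4 cortex libraries (CX_DYT6KO_naive_16, CX_DYT6KO_naive_63, CX_wt_naive_118 and CX_wt_naive_124) and in STR_DYT6KO_crush_8, and miR-337-3p in 3 of 6 crushed Thap1+/- cerebellum libraries (CB_DYT6KO_crush_46, CB_DYT6KO_crush_47 and CB_DYT6KO_crush_86). Sampling at these depths is excluded where a library has its region's usual level, since the smallest count expected from that level was 52.0 and the largest 11288. For miR-337-3p a lack of its hairpin is argued against too, as the other arm was at 1.05 times its usual share (0.988 to 1.14 over 3 cases); for the other miRNAs 0 cases had a measured other arm, so this cannot be told apart there. A step of the counting that drops or reassigns single miRNAs in some libraries may be the source and was not tested, which also leaves open the 0 of miR-3099-3p in all 6 naive wild-type cerebellum libraries.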

How the results depend on the processing

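The fits without let-7 and miR-98 and without the libraries that stand apart were chosen after seeing the data. Leaving out 1 library at a time called these percentages of the miRNAs tested, with that from all libraries in brackets: 8.44 to 39.4 (20.2) for genotype in naive cortex, 0 to 0 (0) for genotype after crush in cortex, 25.7 to 33.3 (34.97) for crush in wild-type cortex, 0 to 3.65 (0.729) for crush in Thap1+/- cortex, 7.89 to 33.2 (13.5) for the cortex interaction, 0 to 12.6 (0) for averaged genotype in cortex, 10.8 to 18.9 (16.6) for averaged crush in cortex, 0 to 0 (0) for genotype in naive striatum, 0 to 0 (0) for genotype after crush in striatum, 0 to 0.513 (0.174) for crush in wild-type striatum, 0 to 0.343 (0) for crush in Thap1+/- striatum, 0 to 0 (0) for the striatum interaction, 0 to 0.171 (0) for averaged genotype in striatum, 0.172 to 3.08 (1.57) for averaged crush in striatum, 0 to 0.178 (0) for genotype in naive cerebellum, 3.72 to 18.996 (13.4) for genotype after crush in cerebellum, 0 to 0 (0) for crush in wild-type cerebellum, 1.06 to 13.6 (5.25) for crush in Thap1+/- cerebellum, 0 to 0.178 (0) for the cerebellum interaction, 6.17 to 22.0 (13.0) for averaged genotype in cerebellum, 1.42 to 11.5 (3.26) for averaged crush in cerebellum, 50.6 to 54.8 (54.6) for striatum against cortex, 64.2 to 69.0 (68.6) for cerebellum against cortex and 65.97 to 68.4 (68.4) for cerebellum against striatum.

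Of the other alternatives, only those whose number of calls moved by over 1.5 times are given, again as percentages. RLE scaling gave 1.28 for crush in Thap1+/- cortex, 0 for crush in wild-type striatum and 0.348 for averaged crush in striatum. Without a filter there were 0 for crush in Thap1+/- cortex, 5.12 for the cortex interaction, 0 for crush in wild-type striatum, 0.302 for averaged crush in striatum, 3.32 for genotype after crush in cerebellum, 1.18 for crush in Thap1+/- cerebellum, 4.28 for averaged genotype in cerebellum and 0.963 for averaged crush in cerebellum, and with a stricter one, which tests fewer miRNAs, 0 for crush in wild-type striatum, 11.2 for averaged crush in cerebellum and 81.7 for cerebellum against cortex. DESeq2 gave 2.55 for crush in Thap1+/- cortex, 20.6 for the cortex interaction, 1.28 for averaged genotype in cortex, 0.174 for genotype after crush in striatum, 0.348 for crush in wild-type striatum, 2.09 for crush in Thap1+/- striatum, 0.174 for averaged genotype in striatum, 4.17 for averaged crush in striatum, 12.8 for crush in Thap1+/- cerebellum, 0.183 for the cerebellum interaction and 11.01 for averaged crush in cerebellum. Fits on the 2 groups alone, which estimate the spread from fewer libraries and from those groups only, gave 0 for genotype in naive cortex, 0 for crush in Thap1+/- cortex, 0 for crush in wild-type striatum, 0.967 for genotype in naive cerebellum, 1.20 for genotype after crush in cerebellum and 1.6 for crush in Thap1+/- cerebellum. Without let-7 and miR-98 there were 8.52 for genotype after crush in cerebellum and 1.85 for averaged crush in cerebellum. Without the libraries that stand apart there were 40.2 for genotype in naive cortex, 4.46 for crush in Thap1+/- cortex, 37.0 for the cortex interaction, 15.4 for averaged genotype in cortex, 0.342 for crush in Thap1+/- striatum, 3.08 for averaged crush in striatum, 1.73 for genotype after crush in cerebellum, 0.692 for crush in Thap1+/- cerebellum, 3.46 for averaged genotype in cerebellum and 1.38 for averaged crush in cerebellum. camera called 0 lists with an estimated correlation in place of 49. Otherwise the cause was not tested.

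Directions turned without CB_wt_crush_3: genotype after crush was 0.20 for miR-141-3p, 0.30 for miR-200a-3p, 0.34 for miR-200c-3p, 0.13 for miR-429-3p and 0.0347 for miR-7a-5p, and crush in wild type -0.23 for miR-141-3p, -0.40 for miR-200a-3p, -0.13 for miR-200c-3p and -0.0919 for miR-429-3p. Over all fits that leave out 1 library, genotype after crush ran in log2 for miR-141-3p -3.62 to 0.20, miR-200a-3p -2.55 to 0.30, miR-200c-3p -3.67 to 0.34, miR-429-3p -2.33 to 0.13 and miR-7a-5p -0.96 to 0.0347, and crush in wild type for miR-141-3p -0.23 to 3.89, miR-200a-3p -0.40 to 2.75, miR-200c-3p -0.13 to 4.103 and miR-429-3p -0.0919 to 2.44. miR-93-5p in striatum against cortex was -0.00300 with RLE scaling and -0.00291 with DESeq2. For named miRNAs and list members, RLE scaling ended the call of 6.49% and added one for 1.98%, DESeq2 3.15% and 10.99%, no filter 12.3% and 0.180%, fits on the 2 groups alone 17.6% and 1.33%, and fits without the libraries that stand apart 20.8% and 10.1%.

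No paired analysis was possible because the groups compared within a region share no library number. Between regions the numbers recur, each in the same genotype and treatment group. Only that of STR_wt_naive_136 and CB_wt_naive_136 has no cortex library. The labels do not tie the numbers to animals. If a number stands for an animal, the main fits between regions treat libraries of the same animal as independent. With the number as a replicate block, striatum against cortex had 55.4% of miRNAs called, cerebellum against cortex 68.4%, cerebellum against striatum 69.1%, and camera called 48 lists. For the effects compared between regions, where this replicate block was chosen after seeing the data, 15.1% were called for crush between striatum and cortex, 22.6% for crush and 19.1% for genotype between cerebellum and cortex, and 0.305% for genotype between cerebellum and striatum, against 13.1%, 23.5%, 19.1% and 0.611% without it. Deviations of same-numbered libraries correlated by 0.0974 between cortex and striatum (mean of 5 pairs, 2 best with their own number), 0.132 between cortex and cerebellum (5 pairs, 4 best) and 0.0767 between striatum and cerebellum (6 pairs, 0 best). Pseudocounts were not tried, as the tables hold counts. Of 1927 miRNAs, 989 had no count in any cortex library, 932 in any striatum and 992 in any cerebellum library. Cerebellum had the highest mean total (11439807 counts) and yet the most miRNAs without a count, so a lower total does not account for its number. For a single miRNA without a count, limited depth and a lack of expression cannot be told apart here.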

Other observations

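The counts over other splits of the libraries were planned, while their adjustment over comparisons and the pairs of hairpin arms were chosen only after the values had been seen. In cortex the 2 arms of some hairpins went opposite ways. There 130 hairpins of a single gene had both arms tested. Both arms passed for 22 after crush in wild type (9 in the same direction, 13 in opposite ones). In naive Thap1+/- cortex both passed for 8 (4 and 4). Over all 130, called or not, 60 went the same way and 70 opposite ways in each of these comparisons. The called pairs were thus split much like all pairs, and a regulation of single arms is not shown. The cortex interaction had 2 called pairs in the same direction and 5 in opposite ones. Averaged genotype in cerebellum had 5 and 0, and naive wild-type cerebellum against cortex 79 and 6. After crush in wild type miR-382-3p rose (0.82 ± 0.21) and miR-382-5p, its abundant arm, fell (-0.63 ± 0.11). In naive Thap1+/- cortex miR-337-3p rose (0.68 ± 0.15) while miR-337-5p fell (-0.37 ± 0.10). In crushed Thap1+/- cerebellum, against wild type, both arms of miR-9, each shared by 3 genes, fell (miR-9-5p -0.44 ± 0.09, miR-9-3p -0.43 ± 0.08).

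For each comparison the libraries were also divided at random, 100 divisions with the real one included, and the number calling at least as many miRNAs was counted. In brackets are the percentage of tested miRNAs called in the real groups and the highest in another division. Such a count does not tell crush or genotype from another difference that follows the groups, such as that of the wild-type naive cortex libraries. Adjusted over the 24 comparisons, the share of such divisions was 0.03 at 1 of 100, where no other division reached the real number and chance is unlikely. That was so for crush in wild-type cortex (34.97, highest other 19.5), averaged crush in cortex (16.6, highest other 0.182), averaged crush in striatum (1.57, highest other 0.348), averaged genotype in cerebellum (13.0, highest other 0.543), averaged crush in cerebellum (3.26, highest other 0), striatum against cortex (54.6, highest other 16.2), cerebellum against cortex (68.6, highest other 28.7) and cerebellum against striatum (68.4, highest other 37.0). The adjusted share was 0.0436 at 2 of 100 for genotype in naive cortex (20.2, highest other 33.2) and genotype after crush in cerebellum (13.4, highest other 17.8). There 1 other division called more than the real groups, so chance is not excluded. The cortex interaction also had 2 of 100 (13.5, highest other 14.03). Its divisions mixed naive and crushed libraries within each genotype, which tests for any crush effect. They cannot decide whether the genotypes differ in it. Only without that adjustment was the share under 0.05 for these: 3 of 100 for crush in Thap1+/- cortex (0.729, highest other 4.55), adjusted share 0.0554, 4 of 100 for crush in wild-type striatum (0.174, highest other 2.96), adjusted share 0.0686 and 3 of 100 for crush in Thap1+/- cerebellum (5.25, highest other 27.0), adjusted share 0.0554. Where the real groups had 0 calls, every division has as many, so this count decides nothing. That holds, at 100 of 100 each, for genotype after crush in cortex (highest other 0.182), averaged genotype in cortex (highest other 13.7), genotype in naive striatum (highest other 0), genotype after crush in striatum (highest other 0.174), crush in Thap1+/- striatum (highest other 0.174), the striatum interaction (highest other 0.522), averaged genotype in striatum (highest other 0), genotype in naive cerebellum (highest other 0.181), crush in wild-type cerebellum (highest other 1.27) and the cerebellum interaction (highest other 15.2). Some divisions called several times the real number for crush in Thap1+/- cortex, in wild-type striatum and in Thap1+/- cerebellum. Only 4, 3 and 5 of the other divisions had any call, so these can be a structure of the libraries or correlated miRNAs that pass together by chance, and neither was tested.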
